A study of Caenorhabditis elegans with 18 samples.

How the data were processed

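RNA was measured in whole Caenorhabditis elegans of 2 strains, the laboratory wild type N2 and lin-35(n745), each at 3 stages: embryos, first-stage larvae (L1) and fourth-stage larvae (L4). lin-35 encodes the single worm member of the retinoblastoma family of pocket proteins, which repress transcription together with E2F and DP factors, and n745 is a premature stop allele. The 18 arrays fall into 6 groups of 3, taken from the sample titles. Per the labels' protocols, the worms were grown on agar plates with the bacterial strain OP50, total RNA was extracted with phenol and cleaned on columns, and cDNA and biotin-labelled cRNA were made by the Affymetrix protocol. The design text states that the 3 samples of a group were grown and isolated independently.

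The deposited values are 1 number per probe set and array, made by the authors with RMA (robust multi-array average) per the submitters' processing notes. RMA corrects background, normalizes the arrays by quantiles and summarises the probes of a probe set. Its version and settings are not given in the sources used here. The authors' deposited values were taken to be on a log2 scale: no label states the base of the logarithm, but the values run from 2.55 to 15.02 with array medians from 6.21 to 6.39, within the range that array scanners give on that scale. Every fold change rests on that reading. RMA gives no detection call, so a low value cannot be told from background, and the number of arrays limits the precision of every value. Scanner files were not used here.

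Of 22625 probe sets, 77 controls were left out and 22548 were tested. Gene names came from the platform annotation: 20766 probe sets name 1 gene, 887 name several and 895 name none. Of the 1-gene probe sets, 20701 were found in the RefSeq gene table of assembly WBcel235 and 65 were not, and 0 symbols needed updating. No genome build is named for the array, so that table served only for names, for chromosomes and for which genes neighbour each other. A gene is represented by the probe set with the highest mean over the 18 arrays among probe sets naming it alone, which gives 17118 genes, of which 2981 have several probe sets. Probe sets of a gene were called in opposite directions for 0 genes in embryos, 7 at L1 (cdk-7, cep-1, exc-7, gei-17, nkcc-1, spd-5 and unc-70) and 1 at L4 (cdc-14). All value columns of the table belong to the 18 samples, so 0 columns were left unused.

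A linear model with 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, no covariate; 12 residual and 7.66 prior degrees of freedom). The groups share 1 estimate of the spread because 3 arrays per group alone give few degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of adjusted p under 0.05. The contrasts were lin-35(n745) minus N2 at each stage, the 3 differences of those effects between stages (interactions), and the 3 differences between stages within N2. The strain contrasts at different stages share no arrays, but they share the estimate of the spread, so their calls are not fully independent. Overlaps of calls were set against the number that independent lists would share. Standard errors are those of the fit and standard deviations are over 3 arrays.

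Gene lists, 22 in number, were fixed before the data were examined, as were the contrasts, the alternatives and the rule for naming genes. They cover DNA replication and S phase, G1 to S regulators, mitosis and chromosome segregation, P granule and germline development, oocyte and maternal genes, meiosis, sperm, small RNA and RNA interference, synMuv and DREAM, intestine, muscle, neuron, hypodermis and seam, collagen and cuticle, molting, embryonic patterning, heat shock and stress, innate immunity, insulin and DAF-16 targets, fasting and lipid metabolism, ribosomal proteins, and DNA damage and apoptosis. Each was tested against all other genes with camera of limma at a preset inter-gene correlation of 0.01, with adjustment over the 22 lists of a contrast, and again with the correlation estimated from the residuals. Some genes are in more than 1 list, and the major sperm protein genes are nearly identical in sequence, so their probe sets can read each other's transcripts.

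The naming rule took, per genotype contrast, the 10 genes with the highest and the 10 with the lowest log2 fold change among called genes whose lin-35(n745) and N2 arrays do not overlap, and up to 4 called genes with the largest change in each list (the 2 with the smallest p where none was called). It took the 10 largest differences per interaction, the 10 genes changed the same way at all 3 stages whose smallest change is largest, the 5 highest and 5 lowest genes of each N2 stage contrast, and lin-35, lin-3, pgl-1, mcm-2, cye-1, rnr-1 and pcn-1 whatever their outcome. The text gives a selection of these.

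The procedure was tested on simulated data of 22548 probe sets, of which 70 were changed by 0.5, 70 by 1 and 60 by 2 log2 units. Of probe sets changed by 1 log2 unit, 97.1% were recovered in embryos, 100% at L1 and 100% at L4. Of those changed by 0.5 units, 41.4%, 55.7% and 58.6% were recovered. For an interaction these shares were 91.4% to 94.3% and 11.4% to 14.3%. The simulated comparisons made 6 to 11 false calls each. Every simulated array had the pooled spread of its probe set. The real lin-35(n745) L1 arrays deviated more from their group mean, with an SD of 0.195 to 0.218 against 0.0939 to 0.144 on the other arrays. The L1 shares and false calls therefore hold for the pooled spread only.

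The alternatives were median centring of each array, a further quantile normalization, a filter at the 40th percentile of mean level, an intensity trend in eBayes, array weights, the arrays of the compared stages alone, a replicate block, 1 probe set per gene, the mean of a gene's probe sets, a threshold of 0.01, an estimated inter-gene correlation, and each array left out in turn. After the hybridization controls had been seen, a block for replicate 1 of both embryo groups and the omission of these arrays were added, for a batch that no label gives and that was inferred from the controls alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.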

Results

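Transcript levels were measured on Affymetrix arrays in whole worms of the wild type N2 and of lin-35(n745), which lacks the worm counterpart of the retinoblastoma protein, in embryos, L1 larvae and L4 larvae. Each of the 6 groups held 3 arrays from independently grown animals. The comparisons ask which transcripts differ between the strains at each stage and whether that difference depends on the stage. Within a group, arrays correlated at 0.9863 to 0.9973 across probe sets, and between groups at up to 0.9917. Identical values were held by 0 pairs of arrays. The first principal component held 71.9% of the variance, the next 16% and the one after 5.07%. Log2 fold changes below are given ± SE with n = 3 arrays per strain, and adjusted p-values are those of limma.

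The lin-35 transcript was lower in every lin-35(n745) array than in every N2 array of its stage. In embryos its log2 level was 9.27 ± 0.17 in N2 and 7.88 ± 0.30 in lin-35(n745) (SD), at L1 7.84 ± 0.02 in N2 and 6.57 ± 0.36 in lin-35(n745), and at L4 7.67 ± 0.06 in N2 and 6.41 ± 0.08 in lin-35(n745). The differences were -1.38 ± 0.15, -1.27 ± 0.15 and -1.25 ± 0.15, with adjusted p = 2.07e-06, 3.29e-06 and 4.35e-06. The single lin-35(n745) arrays read 7.68, 7.75 and 8.22 in embryos, 6.51, 6.24 and 6.95 at L1, and 6.49, 6.43 and 6.32 at L4. A second lin-35 probe set fell by 1.07, 0.86 and 0.77 log2 units. The allele is a point mutation, so its transcript can still be detected.

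**Figure D1:**
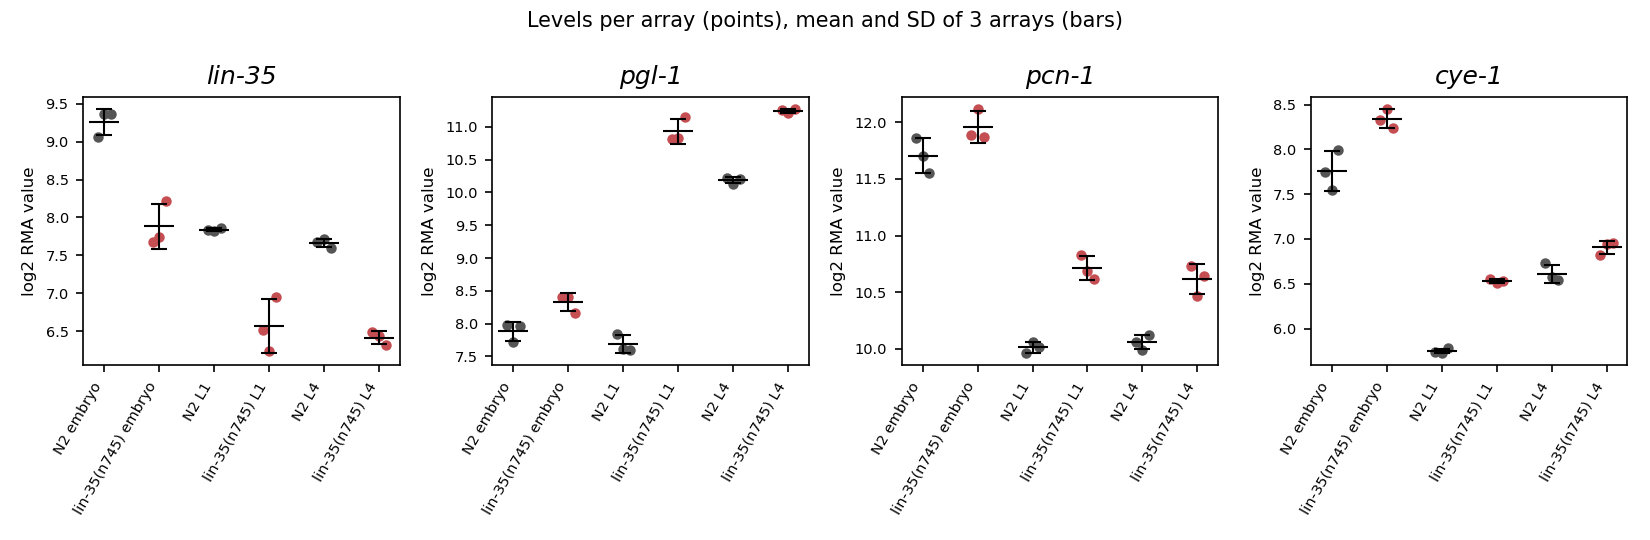
Log2 RMA values (vertical axis) of lin-35, pgl-1, pcn-1 and cye-1 on each array (points), with mean and SD of 3 arrays (bars), in N2 (grey) and lin-35(n745) (red) embryos, L1 and L4 larvae. lin-35 fell by 1.38, 1.27 and 1.25 log2 units at the 3 stages, while pgl-1 rose by 3.25 at L1.

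Development within N2 set the scale for the strain differences. From embryo to L1, collagen genes stood at both ends: col-90 (8.49 ± 0.15), sqt-1 (8.09 ± 0.15) and dpy-5 (7.26 ± 0.11) were among the 5 largest risers, with ZK1025.3 (7.95 ± 0.19) and phat-7 (6.81 ± 0.12). The lowest were ttr-50 (-9.17 ± 0.11), the collagens col-74 (-8.27 ± 0.11) and dpy-14 (-8.06 ± 0.13), mtre-1 (-7.99 ± 0.12) and clec-266 (-7.66 ± 0.12). From L1 to L4 the major sperm protein genes msp-78 (6.17 ± 0.24), msp-31 (6.17 ± 0.24), msp-36 (6.09 ± 0.20) and msp-38 (6.05 ± 0.19) rose with the collagen col-38 (6.16 ± 0.13). The caveolin cav-1 (-5.31 ± 0.13) and the saposin-like spp-12 (-3.69 ± 0.39) were lowest, followed by EGAP4.1 (-3.45 ± 0.18), pud-4 (-3.42 ± 0.19) and T14B1.1 (-3.18 ± 0.10). From embryo to L4, msp-19 (7.22 ± 0.19) was highest and ttr-50 (-9.19 ± 0.11) lowest. These contrasts called 16776 (9207 higher, 7569 lower), 10188 (4769 and 5419) and 16771 (8695 and 8076) of 22548 probe sets. The median change of all probe sets from embryo to L1 was 0.129, and 0.253 after each array was centred on its median.

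The largest strain differences in embryos were increases in lin-35(n745). The beta-tubulin tbb-6 rose by 4.44 ± 0.33 log2 units, from 5.59 ± 0.13 in N2 to 10.03 ± 0.35 in lin-35(n745) (SD, n = 3). It was followed by C09G5.7 (3.79 ± 0.18), F37D6.3 (3.74 ± 0.20), fipr-17 (3.72 ± 0.16), the chemoreceptor genes srd-4 (3.56 ± 0.18) and srh-16 (3.22 ± 0.16), C49G7.12 (3.46 ± 0.19), Y60C6A.1 (3.38 ± 0.20), B0024.4 (3.23 ± 0.17) and F53A9.1 (3.21 ± 0.17). Decreases were smaller: T15D6.8 (-1.96 ± 0.36), gtnt-45 (-1.83 ± 0.27), E03H4.4 (-1.66 ± 0.21), gtnt-46 (-1.60 ± 0.13), the ABC transporter pmp-5 (-1.38 ± 0.25), F36D1.8 (-1.36 ± 0.20), F43H9.4 (-1.36 ± 0.17) and bath-40 (-1.27 ± 0.17). T15D6.8 differed by -1.28 without N2 replicate 3. In all, 2188 of 22548 probe sets passed, 1335 higher and 853 lower, of which 318 and 34 differed by at least 2-fold. Centring each array on its median gave 1240 higher and 1104 lower. Without centring, the lower count was 444 without N2 replicate 3, 557 without lin-35(n745) replicate 1 and 517 without lin-35(n745) replicate 2. On replicate 1 of both strains the hybridization control BioDn read 10.2 and 10.6, and above 12 on the other embryo arrays, while BioB read 5.69 and 6.04 against 4.66 to 5.09. The control CreX showed no such gap, with 11.71 and 11.99 against 11.8 to 12.19. The labels give no batch, so a batch is only inferred from BioDn and BioB. With replicate 1 of both strains as a block 2182 probe sets passed, and 1265 passed without those arrays.

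In the neuron list in embryos, 33 of 87 measured members were higher, 1 lower and 53 not called (38 and 1 adjusted over the list alone). The neuropeptide genes nlp-1 (1.04 ± 0.12), flp-5 (0.98 ± 0.14), flp-8 (0.97 ± 0.10) and flp-4 (0.97 ± 0.11) were highest. The neuron median was 0.24 (camera adjusted p = 1.64e-13, and adjusted p = 0.106 with an estimated correlation). Of the embryonic patterning list, 0 of 57 measured members were higher, 7 lower and 50 not called (0 and 7 adjusted over the list alone). The lower members included sdz-10 (-0.68 ± 0.11) and the proneural factor hlh-14 (-0.60 ± 0.10). The patterning median was -0.171 (camera adjusted p = 0.000837, and adjusted p = 0.106 with an estimated correlation). Within N2, the neuron list had a median change of 0.861 from embryo to L1 and the patterning list one of -1.67. The 200 genes with the largest N2 rise from embryo to L1 had a median strain difference of 0.204 in embryos, and the 200 with the largest fall one of -0.173. Within replicates 2 and 3 the neuron median was 0.194 and within the replicate 1 pair 0.445, and the patterning medians were -0.159 and -0.155.

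In the innate immunity list in embryos, 20 of 60 measured members were higher, 4 lower and 36 not called (25 and 6 adjusted over the list alone). irg-5 (2.62 ± 0.14), the lysozyme gene lys-3 (2.52 ± 0.16) and irg-2 (2.15 ± 0.14) led them. The innate immunity median was 0.195 (camera adjusted p = 1.49e-09, and adjusted p = 0.0535 with an estimated correlation). For heat shock and stress, 8 of 37 measured members were higher, 1 lower and 28 not called (11 and 1 adjusted over the list alone), with the small heat shock gene hsp-17 (1.08 ± 0.11) and the glutathione transferase gst-5 (0.82 ± 0.13) higher and the methionine sulfoxide reductase msra-1 (-0.87 ± 0.13) lower. The heat shock median was 0.185 (camera adjusted p = 0.000373, and adjusted p = 0.106 with an estimated correlation). In the mitosis and chromosome segregation list, 18 of 70 measured members were higher, 1 lower and 51 not called (20 and 2 adjusted over the list alone). The separase gene sep-1 (0.74 ± 0.13), zyg-9 (0.68 ± 0.11) and the kinetochore gene kbp-3 (0.66 ± 0.12) rose. The mitosis median was 0.14 (camera adjusted p = 4.07e-05, and adjusted p = 0.45 with an estimated correlation). In the DNA replication and S phase list, 10 of 45 measured members were higher, 1 lower and 34 not called (11 and 2 adjusted over the list alone), with tipn-1 (0.79 ± 0.12) and the origin recognition gene orc-5 (0.74 ± 0.10) highest. The replication median was 0.127 (camera adjusted p = 0.000643, and adjusted p = 0.533 with an estimated correlation). The replication genes mcm-2 (0.11 ± 0.10), rnr-1 (0.18 ± 0.10) and pcn-1 (0.26 ± 0.11) did not pass. Within replicates 2 and 3 and within the replicate 1 pair, the medians were 0.29 and 0.252 for immunity, 0.0843 and 0.176 for heat shock, 0.128 and 0.144 for mitosis, and 0.139 and 0.137 for replication. The mitosis median was 0.0894 without N2 replicate 2, and the heat shock median 0.105 without N2 replicate 1.

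For the intestine list in embryos, 9 of 61 measured members were higher, 1 lower and 51 not called (11 and 2 adjusted over the list alone), led by the cathepsin B-like cpr-3 (2.2 ± 0.12), the lysozyme lys-1 (1.11 ± 0.14) and the desaturase fat-6 (1.08 ± 0.14). The intestine median was -0.00575 (camera adjusted p = 0.0295, and adjusted p = 0.573 with an estimated correlation). Its median was negative while its mean of 0.144 and its test were positive. That call ended without N2 replicate 1 (adjusted p = 0.0598), N2 replicate 3 (0.102) or lin-35(n745) replicate 1 (0.0519), and without replicate 1 of both strains (0.0941). It also ended with the embryo arrays alone (0.0517), quantile normalization (0.0568) and the level filter (0.13). The intestine median was -0.0284 without N2 replicate 1, 0.0523 without N2 replicate 2, and 0.000819, 0.00399 and -0.0344 without lin-35(n745) replicates 1, 2 and 3 in turn. For insulin and DAF-16 targets, 6 of 47 measured members were higher, 1 lower and 40 not called (8 and 1 adjusted over the list alone), with tts-1 (2.25 ± 0.28) and dod-19 (1.58 ± 0.12) highest. The insulin target median was 0.0351 (camera adjusted p = 0.0123, and adjusted p = 0.305 with an estimated correlation). This call ended without N2 replicate 3 (adjusted p = 0.0815) and with the level filter (0.079), and the median was 0.0873 without N2 replicate 1, 0.074 without lin-35(n745) replicate 2 and 0.0688 without replicate 3. Within replicates 2 and 3 and within the replicate 1 pair the medians were -0.00359 and 0.0521 for intestine and 0.0582 and 0.0682 for insulin targets.

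Other lists did not pass in embryos, although single members did. Germline genes that rose were the P granule genes glh-1 (1.88 ± 0.13) and pgl-3 (1.63 ± 0.10), rnp-8 (0.87 ± 0.11), the synaptonemal complex gene syp-1 (1.46 ± 0.14) and the nuclear Argonaute hrde-1 (0.63 ± 0.10). The E2F gene efl-1 (0.66 ± 0.12), the cyclin E gene cye-1 (0.58 ± 0.10), the DREAM subunit gene lin-9 (0.59 ± 0.12), the repair genes parp-1 (1.04 ± 0.15) and polh-1 (0.91 ± 0.13), the collagens col-103 (2.07 ± 0.13) and col-98 (2.02 ± 0.19) and the patched-related ptr-8 (2.03 ± 0.17) were higher. Of 41 P granule and germline development genes, 5 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.38). Of 38 oocyte and maternal genes, 3 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.657). Of 40 meiosis genes, 3 were higher and 2 lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.945). Of 58 sperm genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.706). Of 47 small RNA and RNA interference genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.714). Of 33 synMuv and DREAM genes, 4 were higher and 4 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.657). Of 19 G1 to S regulators, 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.243). Of 54 DNA damage and apoptosis genes, 6 were higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.105). Of 48 muscle genes, 2 were higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.243). Of 39 hypodermis and seam genes, 1 was higher and 3 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.31). Of the collagen and cuticle genes, 10 were higher and 2 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.714). Of 37 molting genes, 3 were higher and 5 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.38). Of 50 fasting and lipid metabolism genes, 4 were higher and 5 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.714). Of 64 ribosomal protein genes, 1 was higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.657). Median, mean and test differed in sign for the P granule, oocyte, meiosis, small RNA, fasting and collagen lists.

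**Figure D2:**
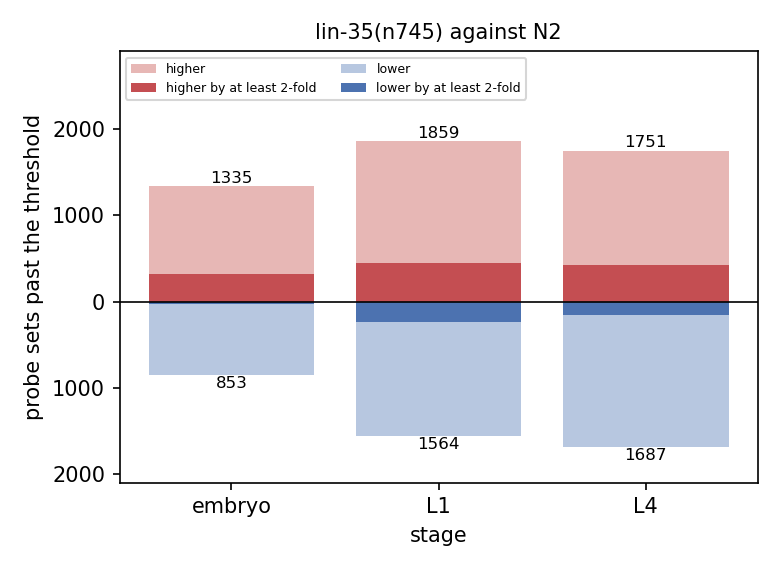
Number of probe sets past the threshold (vertical axis) in lin-35(n745) against N2 at each stage (horizontal axis), higher above the line and lower below it, with the part that differed by at least 2-fold in dark colour. The higher and lower counts were 1335 and 853 in embryos, 1859 and 1564 at L1, and 1751 and 1687 at L4.

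At L1, germline transcripts were among the largest increases. The P granule gene pgl-3 rose by 4.81 ± 0.10 log2 units, from 5.57 ± 0.09 in N2 to 10.38 ± 0.12 in lin-35(n745) (SD, n = 3), and the meiotic axis gene him-3 rose by 4.48 ± 0.12. ddn-1 (5.72 ± 0.20), B0507.8 (5.43 ± 0.29), pals-6 (5.25 ± 0.28), the germline innexin inx-22 (5.17 ± 0.19), F26F2.4 (5.12 ± 0.32), eol-1 (4.62 ± 0.24), Y54G9A.5 (4.54 ± 0.13) and sdz-6 (4.33 ± 0.44) were also highest. The lowest were pud-3 (-5.07 ± 0.15), pud-4 (-4.75 ± 0.19), pmp-5 (-3.20 ± 0.25), spp-12 (-2.97 ± 0.39), gmap-3 (-2.72 ± 0.39), K01D12.9 (-2.60 ± 0.45), the collagen col-91 (-2.51 ± 0.24) and the asparagine synthetase asns-2 (-2.50 ± 0.38). The acyl-CoA dehydrogenase acdh-1 changed by -3.94 ± 1.03, with an SD of 3.94 among the 3 lin-35(n745) arrays, by -1.75 without lin-35(n745) replicate 2, and did not pass with the L1 arrays alone (adjusted p = 0.171). Of 22548 probe sets 3423 passed, 1859 higher and 1564 lower, with 452 and 234 differing by at least 2-fold. Centring each array on its median turned the split to 1569 higher and 2302 lower. The lower count was 1023 without N2 replicate 3. The count rests on a spread pooled over all 6 groups, although the lin-35(n745) L1 arrays differed more among themselves than those of other groups: with the L1 arrays alone 1584 probe sets passed, and 25 of 110 named genes called at L1 no longer did.

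Most measured genes of the replication and mitosis lists rose at L1. In the DNA replication and S phase list, 37 of 45 measured members were higher, 0 lower and 8 not called (41 and 0 adjusted over the list alone). The replication fork gene tipn-1 (2.40 ± 0.12), orc-5 (1.85 ± 0.10), the origin-firing kinase cdc-7 (1.55 ± 0.12) and the DNA ligase lig-1 (1.55 ± 0.11) rose most, and mcm-2 (0.52 ± 0.10) and the sliding clamp pcn-1 (0.70 ± 0.11) rose as well, whereas rnr-1 (0.24 ± 0.10) did not pass. The replication median was 0.698 (camera adjusted p = 5.81e-33, and adjusted p = 0.00618 with an estimated correlation). In the mitosis and chromosome segregation list, 55 of 70 measured members were higher, 0 lower and 15 not called (58 and 1 adjusted over the list alone), led by the kinetochore genes kbp-3 (2.35 ± 0.12) and knl-3 (1.42 ± 0.13) and the condensin hcp-6 (1.55 ± 0.12). The mitosis median was 0.746 (camera adjusted p = 6.95e-41, and adjusted p = 0.00618 with an estimated correlation). Among G1 to S regulators, 10 of 19 measured members were higher, 1 lower and 8 not called (10 and 2 adjusted over the list alone). The DP gene dpl-1 (1.22 ± 0.14), the CDK inhibitor cki-2 (1.06 ± 0.12), efl-1 (1.02 ± 0.12) and cye-1 (0.78 ± 0.10) were higher. The G1 to S median was 0.313 (camera adjusted p = 1.95e-05, and adjusted p = 0.00618 with an estimated correlation). In the DNA damage and apoptosis list, 25 of 54 measured members were higher, 0 lower and 29 not called (27 and 0 adjusted over the list alone), with the translesion polymerase polh-1 (1.76 ± 0.13), parp-1 (1.72 ± 0.15), exo-3 (1.58 ± 0.13) and the mismatch repair gene msh-6 (1.39 ± 0.12) highest. The DNA damage median was 0.311 (camera adjusted p = 5.43e-13, and adjusted p = 0.0346 with an estimated correlation).

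For P granule and germline development at L1, 10 of 41 measured members were higher, 4 lower and 27 not called (11 and 6 adjusted over the list alone). Besides pgl-3, pgl-1 (3.25 ± 0.11), the Vasa-like helicase glh-1 (2.85 ± 0.13) and rnp-8 (2.73 ± 0.11) rose most. The P granule median was 0.0505 (camera adjusted p = 0.00779, and adjusted p = 0.272 with an estimated correlation). In the meiosis list, 12 of 40 measured members were higher, 1 lower and 27 not called (12 and 2 adjusted over the list alone), with syp-1 (3.46 ± 0.14), htp-1 (1.62 ± 0.19) and the cohesin coh-3 (1.48 ± 0.12) after him-3. The meiosis median was 0.0989 (camera adjusted p = 6.95e-05, and adjusted p = 0.166 with an estimated correlation). In the small RNA list, 18 of 47 measured members were higher, 3 lower and 26 not called (18 and 3 adjusted over the list alone), led by hrde-1 (2.98 ± 0.10), the RNA-dependent RNA polymerase rrf-2 (1.48 ± 0.20) and the Argonaute csr-1 (0.91 ± 0.13). The small RNA median was 0.153 (camera adjusted p = 1.97e-05, and adjusted p = 0.0872 with an estimated correlation). Among synMuv and DREAM genes, 11 of 33 measured members were higher, 1 lower and 21 not called (12 and 1 adjusted over the list alone), with lin-9 (1.13 ± 0.12) and lin-13 (1.10 ± 0.12) higher and lin-35 the lower one. The synMuv median was 0.233 (camera adjusted p = 1.53e-05, and adjusted p = 0.0872 with an estimated correlation). In the neuron list, 10 of 87 measured members were higher, 0 lower and 77 not called (10 and 0 adjusted over the list alone), among them ric-19 (0.78 ± 0.12) and nlp-10 (0.57 ± 0.11). The neuron median was 0.144 (camera adjusted p = 0.00162, and adjusted p = 0.406 with an estimated correlation). In the innate immunity list, 13 of 60 measured members were higher, 6 lower and 41 not called (16 and 6 adjusted over the list alone), with the C-type lectins clec-60 (3.02 ± 0.25), clec-61 (2.67 ± 0.13) and clec-67 (1.80 ± 0.13) highest. The innate immunity median was 0.109 (camera adjusted p = 0.00507, and adjusted p = 0.201 with an estimated correlation). The immunity call ended without lin-35(n745) replicate 1 (adjusted p = 0.0647) or 2 (0.0668), where the median was 0.0403 without the latter and 0.178 without replicate 3. The P granule median was 0.029, 0.129 and 0.0254 without N2 replicates 1, 2 and 3 in turn, and 0.165, 0.0097 and -0.0239 without those of lin-35(n745), and the list passed each time. The meiosis median was 0.155 without N2 replicate 1 and 0.045 without lin-35(n745) replicate 3, the neuron median 0.0703 without the latter, and the synMuv median 0.35 without lin-35(n745) replicate 2.

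Lower lists at L1 covered the cuticle, lipid metabolism, sperm, intestine and muscle. For collagen and cuticle, 2 members were higher and 36 lower (3 and 45 adjusted over the list alone), with col-39 (-2.43 ± 0.31) and col-91 lowest. The collagen median was -0.27 (camera adjusted p = 2.38e-10, and adjusted p = 0.155 with an estimated correlation). The list mean was 7.90, 8.26 and 7.87 on the lin-35(n745) arrays and 8.40, 8.36 and 8.35 on those of N2, so replicates 1 and 3 carried most of the decrease, and the median was -0.377 without lin-35(n745) replicate 2. For fasting and lipid metabolism, 1 of 50 measured members was higher, 12 lower and 37 not called (4 and 20 adjusted over the list alone), including the fatty acid elongase elo-6 (-1.04 ± 0.16). The fasting list median was -0.251 (camera adjusted p = 9.4e-05, and adjusted p = 0.139 with an estimated correlation). In the sperm list, 0 of 58 measured members were higher, 14 lower and 44 not called (0 and 21 adjusted over the list alone), including msp-19 (-1.04 ± 0.19) and msd-2 (-0.95 ± 0.14). The sperm median was -0.247 (camera adjusted p = 1.19e-05, and adjusted p = 0.139 with an estimated correlation). In the intestine list, 6 of 61 measured members were higher, 17 lower and 38 not called (6 and 20 adjusted over the list alone), with cpr-3 rising by 1.59 ± 0.12 against the list. The intestine median was -0.182 (camera adjusted p = 0.0159, and adjusted p = 0.397 with an estimated correlation). In the muscle list, 1 of 48 measured members was higher, 4 lower and 43 not called (1 and 4 adjusted over the list alone), with the troponin T tnt-3 (-0.67 ± 0.11) lower. The muscle median was -0.141 (camera adjusted p = 0.0124, and adjusted p = 0.416 with an estimated correlation). N2 replicate 1 held more of the adult transcripts than the other N2 L1 arrays: its mean over the sperm list was 5.79 against 5.51 and 5.48, and 5.22, 5.36 and 5.30 in lin-35(n745), and the yolk protein gene vit-4 read 8.77 against 6.06 and 6.92. Without that array the sperm median was -0.197 and the intestine median -0.14, and both lists still passed. The intestine call ended without lin-35(n745) replicate 2 (median -0.103, adjusted p = 0.0982) and the muscle call without replicate 3 (-0.0845, 0.308).

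The remaining lists did not pass at L1. Of 38 oocyte and maternal genes, 5 were higher and 9 lower (5 and 11 adjusted over the list alone, camera adjusted p = 0.272). Of 39 hypodermis and seam genes, 5 were higher and 5 lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.222). Of 37 molting genes, 5 were higher and 5 lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.598). Of 57 embryonic patterning genes, 5 were higher and 3 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.598). Of 37 heat shock and stress genes, 3 were higher and 8 lower (3 and 8 adjusted over the list alone, camera adjusted p = 0.222). Of 47 insulin and DAF-16 targets, 5 were higher and 4 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.247). Of 64 ribosomal protein genes, 0 were higher and 1 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.323). Single members that changed were the oocyte genes spn-4 (1.06 ± 0.14) and par-2 (0.94 ± 0.13), the fusogen eff-1 (0.91 ± 0.12), the gut factors elt-7 (-0.76 ± 0.11) and elt-2 (0.54 ± 0.09), msra-1 (-1.05 ± 0.13) and dod-23 (1.76 ± 0.15). For the molting list the median was positive and the mean negative, and for patterning the median was negative and the test positive. The epidermal growth factor gene lin-3, a known target of the synMuv genes, differed by 0.41 ± 0.11 in embryos (adjusted p = 0.0214), 0.08 ± 0.11 at L1 (0.714) and 0.05 ± 0.11 at L4 (0.861). The embryo call for lin-3 ended without N2 replicate 1 (adjusted p = 0.0913) or 3 (0.106), or without lin-35(n745) replicate 1 (0.0736) or 3 (0.0757).

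**Figure D3:**
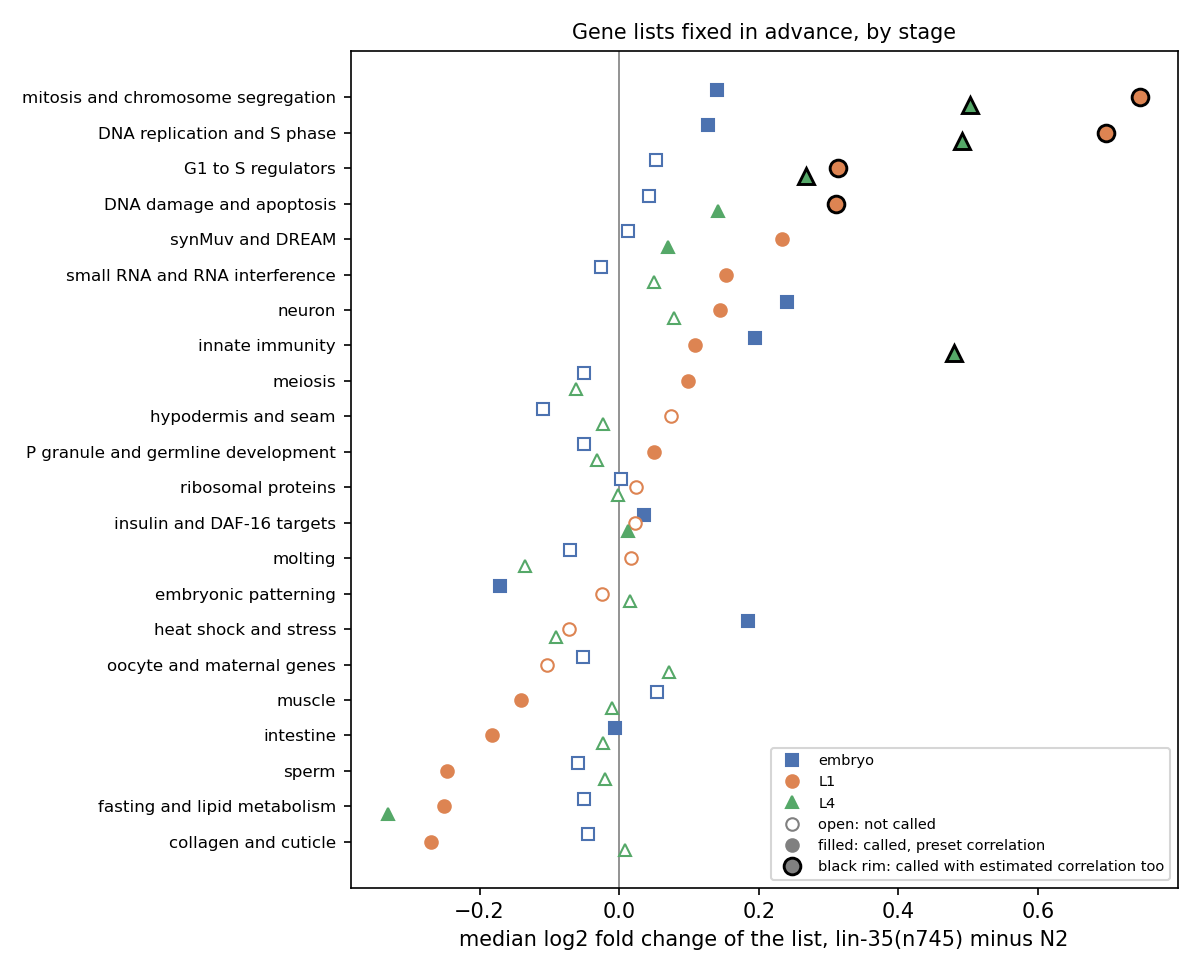
Median log2 fold change of each gene list in lin-35(n745) minus N2 (horizontal axis) in embryos (squares), at L1 (circles) and at L4 (triangles), filled where camera called the list with the preset correlation and black-rimmed where the call held with an estimated correlation. The mitosis and replication lists stood at 0.746 and 0.698 at L1 and at 0.502 and 0.491 at L4.

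At L4, B0348.2 rose by 5.77 ± 0.35 log2 units, from 6.24 ± 0.27 in N2 to 12.01 ± 0.03 in lin-35(n745) (SD, n = 3), and the lectin gene clec-47 fell most, with -5.51 ± 0.23. Other large increases were the claudin-like clc-11 (4.85 ± 0.28), T19C9.8 (4.60 ± 0.20), the ribonuclease H gene rnh-1.3 (4.29 ± 0.14), F37D6.3 (4.08 ± 0.20), the lectins clec-61 (3.98 ± 0.13) and clec-60 (3.97 ± 0.25), ddn-1 (3.95 ± 0.20), C08E8.4 (3.95 ± 0.12) and pals-6 (3.93 ± 0.28). The aspartyl protease asp-12 (-4.37 ± 0.15), nspe-7 (-3.45 ± 0.31), Y17D7B.7 (-3.19 ± 0.11), pmp-5 (-2.68 ± 0.25), Y48E1B.8 (-2.50 ± 0.21), msra-1 (-2.38 ± 0.13), Y38E10A.14 (-2.36 ± 0.23) and the yolk protein genes vit-4 (-2.35 ± 0.40) and vit-5 (-2.35 ± 0.41) followed. Of 22548 probe sets 3438 passed, 1751 higher and 1687 lower, and 569 differed by at least 2-fold, 418 of them higher. Centring each array on its median turned the split to 1590 higher and 2108 lower, and quantile normalization to 1755 and 1884, while 4815 passed with the L4 arrays alone and 6687 with array weights. The lower count was 1070 without lin-35(n745) replicate 2. The 5' minus 3' difference of the GAPDH control probe sets averaged 0.126 in N2 and -0.0293 in lin-35(n745) L4 arrays, and -0.204 and -0.344 at L1.

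The mitosis, replication and immunity lists held the most increases at L4. In the DNA replication and S phase list, 31 of 45 measured members were higher, 0 lower and 14 not called (36 and 0 adjusted over the list alone), led by tipn-1 (2.04 ± 0.12), lig-1 (1.28 ± 0.11), the replicative helicase mcm-7 (1.22 ± 0.11) and exo-1 (1.20 ± 0.11). The replication median was 0.491 (camera adjusted p = 5.95e-23, and adjusted p = 0.0232 with an estimated correlation). rnr-1 (0.51 ± 0.10) and pcn-1 (0.55 ± 0.11) rose, while mcm-2 (0.17 ± 0.10) and cye-1 (0.30 ± 0.10) did not pass. With array weights both passed (adjusted p = 0.0306 and 0.00237), and cye-1 also passed with the L4 arrays alone (0.0336), quantile normalization (0.0477) and the level filter (0.0465). In the mitosis list, 47 of 70 measured members were higher, 0 lower and 23 not called (54 and 0 adjusted over the list alone), with kbp-3 (1.78 ± 0.12), mis-12 (1.35 ± 0.10) and hcp-6 (1.35 ± 0.12) highest. The mitosis median was 0.502 (camera adjusted p = 1.09e-27, and adjusted p = 0.0226 with an estimated correlation). Among G1 to S regulators, 7 of 19 measured members were higher, 1 lower and 11 not called (9 and 1 adjusted over the list alone), with efl-1 (1.11 ± 0.12) and dpl-1 (0.96 ± 0.14) highest. The G1 to S median was 0.268 (camera adjusted p = 0.00154, and adjusted p = 0.0232 with an estimated correlation). In the innate immunity list, 31 of 60 measured members were higher, 8 lower and 21 not called (33 and 9 adjusted over the list alone), with irg-3 (2.83 ± 0.20) high beside the lectins clec-61 and clec-60. The innate immunity median was 0.479 (camera adjusted p = 3.46e-10, and adjusted p = 0.0226 with an estimated correlation). For DNA damage and apoptosis, 15 of 54 measured members were higher, 2 lower and 37 not called (17 and 2 adjusted over the list alone), including the end-joining gene cku-80 (1.23 ± 0.12) and polh-1 (1.17 ± 0.13). The DNA damage median was 0.141 (camera adjusted p = 5.92e-05, and adjusted p = 0.278 with an estimated correlation).

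In the synMuv and DREAM list at L4, 9 of 33 measured members were higher, 2 lower and 22 not called (11 and 3 adjusted over the list alone), with lin-36 (0.92 ± 0.15) higher and lin-35 among the lower. The synMuv median was 0.0706 (camera adjusted p = 0.00796, and adjusted p = 0.305 with an estimated correlation). For insulin and DAF-16 targets, 8 of 47 measured members were higher, 4 lower and 35 not called (9 and 4 adjusted over the list alone), with dod-20 (2.68 ± 0.12), dod-23 (2.52 ± 0.15) and the insulin-like peptide ins-35 (2.08 ± 0.14) highest. The insulin target median was 0.0122 (camera adjusted p = 0.0354, and adjusted p = 0.305 with an estimated correlation). That call ended without lin-35(n745) replicate 3 (adjusted p = 0.0587), where the median was -0.0154, and with a further quantile normalization the median was -0.00268 (0.0716). It also ended with the level filter (adjusted p = 0.142) and with the mean of a gene's probe sets (0.0838). Without N2 replicates 1, 2 and 3 in turn the insulin target median was 0.0568, -0.0165 and 0.0038, and without lin-35(n745) replicates 1 and 2 it was 0.00577 and 0.0195. The synMuv median was 0.109 without lin-35(n745) replicate 1. For fasting and lipid metabolism at L4, 2 of 50 measured members were higher, 17 lower and 31 not called (3 and 25 adjusted over the list alone). The desaturase fat-7 (-1.50 ± 0.17), acdh-2 (-1.51 ± 0.35) and ech-6 (-1.33 ± 0.25) fell, and the lipase lipl-2 (1.19 ± 0.11) rose. The fasting list median was -0.331 (camera adjusted p = 0.000496, and adjusted p = 0.253 with an estimated correlation).

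In other L4 lists, pgl-3 (1.98 ± 0.10), pgl-1 (1.06 ± 0.11), syp-1 (1.67 ± 0.14), him-3 (1.26 ± 0.12), hrde-1 (1.77 ± 0.10), ric-19 (0.89 ± 0.12), cpr-3 (2.05 ± 0.12) and gst-5 (1.55 ± 0.13) rose. The collagens col-181 (-2.04 ± 0.13) and the adult-specific col-19 (-1.35 ± 0.15), the sperm regulator spe-44 (-0.98 ± 0.16), wrt-2 (-0.68 ± 0.10), nas-37 (-0.81 ± 0.16) and vit-2 (-1.72 ± 0.29) fell. Whether the L4 larvae of the strains were of the same age was not tested. The lists themselves did not pass. Of 41 P granule and germline development genes, 8 were higher and 7 lower (8 and 9 adjusted over the list alone, camera adjusted p = 0.853). Of 38 oocyte and maternal genes, 3 were higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.179). Of 40 meiosis genes, 7 were higher and 6 lower (9 and 9 adjusted over the list alone, camera adjusted p = 0.958). Of 58 sperm genes, 0 were higher and 7 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.603). Of 47 small RNA and RNA interference genes, 11 were higher and 3 lower (13 and 6 adjusted over the list alone, camera adjusted p = 0.0538). Of 61 intestine genes, 9 were higher and 11 lower (11 and 14 adjusted over the list alone, camera adjusted p = 0.958). Of 48 muscle genes, 2 were higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.881). Of 87 neuron genes, 4 were higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.0717). Of 39 hypodermis and seam genes, 4 were higher and 3 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.881). Of the collagen and cuticle genes, 9 were higher and 24 lower (9 and 27 adjusted over the list alone, camera adjusted p = 0.853). Of 37 molting genes, 3 were higher and 7 lower (3 and 8 adjusted over the list alone, camera adjusted p = 0.599). Of 57 embryonic patterning genes, 3 were higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.603). Of 37 heat shock and stress genes, 7 were higher and 7 lower (8 and 9 adjusted over the list alone, camera adjusted p = 0.881). Of 64 ribosomal protein genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.881). Median, mean and test differed in sign for the P granule, intestine, muscle, hypodermis, collagen and ribosomal lists. Of the 66 list tests over the 3 stages 31 passed, and 8 passed with an estimated correlation. Regrouped arrays passed a median of 18 list tests at the preset correlation.

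Many genes changed in the same direction at every stage. The 10 with the largest change at their weakest stage were all higher, with log2 fold changes in embryos, at L1 and at L4 of 4.44, 2.50 and 3.29 for tbb-6. They were F37D6.3 (3.74, 4.02 and 4.08), rnh-1.3 (2.32, 4.20 and 4.29), skr-5 (2.31, 2.40 and 3.66), which encodes a Skp1-related protein, C08E8.4 (2.23, 2.96 and 3.95) and C54D10.10 (2.46, 3.19 and 2.14). The others were the ABC transporter wht-3 (2.54, 2.67 and 2.05), srh-16 (3.22, 2.40 and 2.13), Y37H2A.14 (2.03, 2.85 and 3.43) and C09G5.7 (3.79, 2.03 and 2.0). Among 17118 genes, 308 were higher at all 3 stages against 7.67 for independent lists, and 53 were lower against 3.89. The lower count was 98 without lin-35(n745) L1 replicate 1 and 35 without lin-35(n745) embryo replicate 2. In pairs, 431 genes were higher in embryos and at L1 (93 for independent lists), 441 in embryos and at L4 (88) and 734 at L1 and L4. The lower counts were 97 in embryos and at L1 (48 for independent lists) and 330 at L1 and L4 (94.5). Opposite calls numbered 63 for embryos and L1, 61 for embryos and L4 and 76 for L1 and L4. One-sided Fisher's exact tests across genes, which are not independent replicates, gave p of at most 1.71e-11 for the same-direction pairs. Effects correlated across genes at r = 0.334 for embryos and L1 (Spearman 0.208), 0.371 for embryos and L4 (0.254) and 0.546 for L1 and L4 (0.344). A call was made at any stage for 5245 genes and at 1 stage for 3653.

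The strain difference itself depended on the stage for many genes. Between embryo and L1, pud-3 (-5.10 ± 0.21), pud-4 (-4.28 ± 0.27) and the cuticle-related grl-21 (-4.59 ± 0.77) had a lower difference at L1, and F26F2.4 (5.06 ± 0.45), sdz-6 (4.93 ± 0.63), ddn-1 (4.59 ± 0.29), pals-6 (4.53 ± 0.39) and him-3 (4.17 ± 0.17) a higher one. Between embryo and L4, nspe-7 (-6.47 ± 0.43), clec-47 (-5.38 ± 0.33), Y38E10A.14 (-5.24 ± 0.32), asp-12 (-5.15 ± 0.21) and irg-5 (-4.10 ± 0.19) had a lower difference at L4, and T19C9.8 (4.14 ± 0.29), B0348.2 (4.09 ± 0.50) and clec-61 (4.03 ± 0.19) a higher one. nspe-7 changed direction, rising by 3.02 in embryos and reaching -3.45 at L4, as did irg-5 (2.62 and -1.48) and Y38E10A.14 (2.88 and -2.36). Between L1 and L4, clec-47 (-6.12 ± 0.33), asp-12 (-4.33 ± 0.21) and him-3 (-3.22 ± 0.17) were lower and cyp-14A5 (3.04 ± 0.27), a cytochrome P450 gene, was higher. The interactions called 2074 probe sets for L1 against embryo (1090 higher, 984 lower), 1746 for L4 against embryo (867 and 879) and 1515 for L4 against L1 (764 and 751), with a median SE of 0.172. The last count was 2447, with 1305 lower, without lin-35(n745) L1 replicate 2. After each array was centred on its median, L1 against embryo had 990 higher and 1092 lower.

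Cell cycle lists differed more between the strains at L1 than in embryos. In the replication list 24 of 45 measured members were higher, 0 lower and 21 not called (30 and 0 adjusted over the list alone). The replication median was 0.591 (camera adjusted p = 1.83e-20, and adjusted p = 0.0373 with an estimated correlation). In the mitosis list 40 of 70 measured members were higher, 0 lower and 30 not called (47 and 0 adjusted over the list alone). The mitosis median was 0.559 (camera adjusted p = 5.09e-24, and adjusted p = 0.0373 with an estimated correlation). In the G1 to S list 4 of 19 measured members were higher, 0 lower and 15 not called (5 and 0 adjusted over the list alone). The G1 to S median was 0.246 (camera adjusted p = 0.00124, and adjusted p = 0.0373 with an estimated correlation). The heat shock list shifted the other way, where 1 of 37 measured members was higher, 8 lower and 28 not called (1 and 10 adjusted over the list alone). The heat shock median was -0.204 (camera adjusted p = 4.3e-05, and adjusted p = 0.0373 with an estimated correlation). Of the 22 lists, 18 passed for L1 against embryo, 4 of them with an estimated correlation. For L4 against embryo 8 passed and for L4 against L1 12 passed, and with an estimated correlation 0 and 0.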

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

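The tests of L1 larvae further along development, of an inferred embryo hybridization batch, of strain background linked to lin-35 and of probe sets shared between related genes were chosen after the result was seen.

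Single genes stood out because the strain difference itself differed between stages in a test of that difference. Between embryo and L1 the difference in log2 fold change was -5.10 for pud-3, 5.06 for F26F2.4, 4.93 for sdz-6, 4.59 for ddn-1, -4.59 for grl-21, 4.585 for B0507.8, 4.525 for pals-6, 4.41 for F26F2.3, -4.28 for pud-4 and 4.17 for him-3. Between embryo and L4 it was -6.47 for nspe-7, -5.38 for clec-47, -5.235 for Y38E10A.14, -5.15 for asp-12, 4.145 for T19C9.8, -4.10 for irg-5, 4.09 for B0348.2, 4.03 for clec-61, 3.94 for clec-60 and 3.78 for clc-11. Between L1 and L4 it was -6.12 for clec-47, -4.33 for asp-12, -4.24 for nspe-7, 3.32 for F48G7.8, -3.31 for C43D7.4, -3.22 for him-3, 3.05 for W08E12.2, 3.04 for cyp-14A5, -3.03 for Y17D7B.7 and 3.02 for C32H11.4.

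The interactions called 2074 probe sets for L1 against embryo, 1746 for L4 against embryo and 1515 for L4 against L1. Of 100 drawn joint splits of the arrays, 2 gave as many for each of them, the real split included, a share under 0.05. Most other splits mix the strains within a group, which raises the spread and lowers the calls, so this does not exclude chance. The highest other splits gave 3810, 4046 and 4930 and point to a structure of the samples: they keep the real groups and swap the strains at 1 stage, which turns a difference of effects into their sum. The highest of the remaining 98 splits gave 1546, 1524 and 1428.

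Gene lists whose strain difference was larger or smaller at L1 than in embryos had these medians: replication 0.591, G1 to S 0.246, mitosis 0.559, P granule 0.102, meiosis 0.187, sperm -0.224, small RNA 0.193, synMuv 0.237, intestine -0.3, muscle -0.208, neuron -0.167, hypodermis 0.2, collagen -0.247, patterning 0.138, heat shock -0.204, innate immunity -0.201, fasting -0.251 and DNA damage 0.327. With an estimated correlation replication, G1 to S, mitosis and heat shock passed (adjusted p = 0.0373 each) and the other 14 lists did not. The calls ended for muscle (-0.131, adjusted p = 0.0633) and innate immunity (-0.118, 0.0876) without lin-35(n745) L1 replicate 3. The hypodermis call ended without N2 L1 replicate 1 (adjusted p = 0.0752), N2 embryo replicate 2 (0.0646), lin-35(n745) embryo replicate 2 (0.0507), or lin-35(n745) L1 replicate 2 (0.0808) or 3 (0.0731), and with the level filter (0.1), array weights (0.0579) or the mean of a gene's probe sets (median 0.0835, adjusted p = 0.135). Single arrays moved other medians: P granule to 0.178 and 0.0546 without lin-35(n745) L1 replicates 1 and 2, and fasting to -0.383 without replicate 1. The meiosis median was 0.124 without lin-35(n745) L1 replicate 3, the sperm median -0.142 without N2 L1 replicate 1, and the intestine median -0.451 without N2 embryo replicate 2.

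For L4 against embryo the medians were 0.392 for replication, 0.365 for mitosis, 0.14 for synMuv, -0.21 for neuron, 0.201 for patterning, -0.289 for heat shock, -0.332 for fasting and 0.159 for DNA damage, and 0 of these lists passed with an estimated correlation. The calls for synMuv and DNA damage ended without N2 L4 replicate 3 (adjusted p = 0.0557 for both). DNA damage also ended without lin-35(n745) L4 replicate 1 (0.0569), N2 embryo replicate 3 (0.113) or lin-35(n745) embryo replicate 3 (0.0663). The patterning median was 0.123 without N2 embryo replicate 3. For L4 against L1 the medians were -0.158 for replication, -0.204 for mitosis, -0.135 for P granule, 0.188 for oocyte, -0.273 for meiosis, 0.21 for sperm, -0.155 for small RNA, 0.117 for intestine, 0.138 for muscle, 0.258 for collagen, 0.45 for innate immunity and -0.182 for DNA damage, and 0 passed with an estimated correlation. The oocyte call ended without N2 L1 replicate 1 (0.0257, adjusted p = 0.489), lin-35(n745) L1 replicate 1 (0.0898, 0.225) or N2 L4 replicate 1 (adjusted p = 0.0537), or with array weights (0.0778). The small RNA call (-0.0768, 0.0737) and the muscle call (0.0389, 0.357) ended without lin-35(n745) L1 replicate 3. The intestine call ended without N2 L1 replicate 1 (0.0546, adjusted p = 0.29), lin-35(n745) L1 replicate 2 (0.0653, 0.125) or 3 (adjusted p = 0.106), or N2 L4 replicate 3 (0.0532), and its median was 0.075 without lin-35(n745) L4 replicate 3.

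Other splits of the arrays were also counted for the remaining comparisons. For each stage 1 of the 10 splits of the 6 arrays, the real one, gave as many probe sets, which is too few splits for a share under 0.05: 2188 against at most 2 in embryos, 3423 against at most 7 at L1 and 3438 against at most 0 at L4. The N2 stage contrasts gave 1 of 10 likewise, with 16776, 10188 and 16771 against at most 0. For genes changed the same way at all 3 stages 1 of 100 drawn splits reached 361 and the highest other gave 0, a share under 0.05. Splits that mix the strains made at most 7 calls at a stage. A shared count near 0 was thus fixed in advance for them, and the splits do not exclude chance. For the gene lists 2 of 100 drawn splits gave 31 list tests, the real one and 1 other. That share is under 0.05, but a regrouping matched the real count, so chance is not excluded for the number of lists. The median of the other splits was 18 list tests, so the preset correlation calls many lists in regrouped arrays, and a single list call at that setting carries little weight.

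Most measured genes of the replication and mitosis lists were higher in lin-35(n745) L1 larvae, with medians of 0.698 for replication and 0.746 for mitosis. Embryos or embryonic RNA carried over would raise the genes highest in embryos, but the 100 genes with the largest N2 embryo minus L1 difference (median 5.37) had a median strain difference of -0.0889 (-0.123 to -0.075 without single arrays). At least 92.5% of both shifts was kept under 2 other scalings. Both start from values that RMA had already normalized, so they cannot show what that first normalization did, and array normalization stays open. Larvae further along development would raise the genes that rise from L1 to L4 in N2 and lower those that fall. The 200 largest fallers were lower as this needs (-0.183, -0.229 to -0.138), but the 200 largest risers were lower too (-0.147, -0.181 to -0.107). The risers include major sperm protein genes such as msp-78, which a small lead within L1 need not raise. The test therefore cannot decide an age difference within L1, which stays open. A direct effect of the genotype stays open as a hypothesis and was not tested apart from other differences between the strains.

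In lin-35(n745) embryos 33 of 87 neuron genes were higher and 7 of 57 embryonic patterning genes lower, and for both lists adjusted p = 0.106 with an estimated correlation. A hybridization batch of the embryo arrays was inferred from the hybridization controls and is given by no label. It would hold replicate 1 of both strains, so a shift common to both strains cancels from the strain difference by design. At least 80.7% of both shifts was kept within replicates 2 and 3 and within the replicate 1 pair. The neuron median was 0.194 in the former and 0.445 in the latter. These medians cannot decide whether a batch acted differently on the strains. Older lin-35(n745) embryos stay open: the 200 genes with the largest N2 rise from embryo to L1 were higher (median 0.204, 0.197 to 0.258 without single arrays) and the 200 with the largest fall lower (-0.173, -0.205 to -0.123). The same medians were 0.0115 and -0.00759 in arrays simulated without a strain difference. A difference in embryo age and an effect of the genotype itself are both open.

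Genes changed the same way at all 3 stages could come from strain background beside lin-35, but 1.39% of them lay among the 300 annotated genes on either side of it, where 2.24% of the measured genes lie. Probe sets shared between related genes are argued against as the whole cause, since the number was 33.5 times that of independent lists among genes whose probe sets are not marked as shared. An effect of the genotype stays open as a hypothesis, and background elsewhere in the genome was not tested.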

How the results depend on the processing

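The alternatives with embryo replicate 1 of both strains, a batch inferred from the BioDn control, as a block or left out were chosen after the data were seen, and the other alternatives were planned.

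Named genes changed little in direction across the alternatives run. Of the named genes past the threshold, 73 of 100 in embryos, 85 of 110 at L1 and 89 at L4 (with 14 that did not) stayed past it in the same direction under every alternative that tested them, and so did the 10 of each interaction and of each N2 contrast. The filter at the 40th percentile of mean level tested 85 of these called genes in embryos, all but 9 at L1, and 97 at L4. It tested 4, 10 and 9 of those of the interactions of L1 with embryo, L4 with embryo and L4 with L1, and 8 of those of N2 L4 against L1. At L4 cye-1, mcm-2 and rpl-5, not past the threshold, passed it with array weights (adjusted p = 0.00237, 0.0306 and 0.0486). The epidermal growth factor gene lin-3 at L4, which did not pass, changed sign, to -0.00114 with array weights and -0.0017 without N2 replicate 1, in a range up to 0.118 with other single arrays left out. The lin-35 level stayed lower with each array left out, at -1.55 to -1.28 in embryos, -1.46 to -1.11 at L1 and -1.29 to -1.21 at L4.

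A threshold of 0.01 on the adjusted p gave 1141 probe sets in embryos, 1969 at L1, 2137 at L4, 1004, 964 and 698 for the interactions of L1 with embryo, L4 with embryo and L4 with L1, and 210 genes shared between stages, lower by construction. Array weights gave 6687 at L4 and 3098 for the interaction of L4 with embryo. The weights were 0.45 to 0.491 for the lin-35(n745) L1 arrays and 0.83 to 3.83 for the L4 arrays, and the cause was not tested further. With the arrays of the compared stages alone, 1584 passed at L1 and 1323 for the interaction of L1 with embryo, while 4815 passed at L4 and 2523 for the interaction of L4 with embryo. The main counts rest on a spread pooled over all groups. The SD from the group mean was 0.195 to 0.218 on the lin-35(n745) L1 arrays and 0.0939 to 0.129 on the L4 arrays. A filter at the 40th percentile of mean level gave 10865 for N2 L1 against embryo and 11052 for N2 L4 against embryo, since fewer probe sets were tested. Without embryo replicate 1 of both strains, with 4 embryo arrays, 1265 passed in embryos, and with these arrays as a block 2182.

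With an estimated correlation 8 of 66 list tests passed, in place of 31, since the setting allows for genes that move together. The lists that passed under every alternative numbered 0 of 8 in embryos, 4 of 15 at L1 and 4 of 8 at L4, and for the interactions 4 of 18, 0 of 8 and 0 of 12.

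With each array left out in turn, the counts ran from 1499 to 1855 in embryos, 2399 to 4067 at L1 and 2548 to 2931 at L4. The interactions ran from 1540 to 2881, 1350 to 1662 and 1021 to 2447, the last without lin-35(n745) L1 replicate 2. The N2 contrasts ran from 15811 to 16185 for L1 against embryo, 8930 to 9379 for L4 against L1 and 15635 to 16203 for L4 against embryo. Genes shared between stages ran from 274 to 408, and list tests past the threshold from 29 to 33.

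The replicate numbers were checked for pairing: after removal of group means, same-number arrays of the strains correlated at -0.0521 to 0.269, and not every array correlated best with its own number. With a replicate block 2069, 3434 and 3336 probe sets passed at the 3 stages, and 2020, 1740 and 1520 for the interactions. The block takes replicate 1 as its reference, so the N2 contrasts then compared the fitted replicate 1 levels of the stages. They gave 13331, 7353 and 13736 probe sets, which do not test pairing in these contrasts. With the block 365 genes were shared and 32 list tests passed. RMA values give no signal over background, so low values limit the fold that can be read from them, and this limit was not measured here.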

Other observations

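All tests of this part, on gene families, chromosomes, neighbouring genes and single arrays, were chosen after the data were seen.

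Many genes of the pals family, which respond to intracellular infection, were higher in lin-35(n745) larvae. At L1 19 of 23 measured members were higher and 0 lower, with a median log2 fold change of 2.17 (1.86 to 2.56 without single arrays, 2.11 after centring, 2.23 after quantile normalization). The camera adjusted p was 4.34e-24, and adjusted p = 0.137 with an estimated correlation. The largest changes were 5.25 for pals-6, 3.72 for pals-28 and 2.99 for pals-5. At L4 15 members were higher and 0 lower (median 0.749, adjusted p = 6.03e-12, and adjusted p = 0.613 with an estimated correlation), and in embryos 1 was higher and 2 lower (median 0.24, adjusted p = 0.116). The family mean read 4.33, 4.35 and 4.33 on the N2 L1 arrays and 6.81, 6.64 and 5.81 on those of lin-35(n745). The strain difference was larger at L1 than in embryos by a median of 1.93 (adjusted p = 8.04e-19, and adjusted p = 0.453 with an estimated correlation).

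Among mitochondrial ribosomal protein genes at L4, 22 of 34 mrpl genes fell with a median of -0.424 (-0.457 after centring, -0.398 after quantile normalization, adjusted p = 6.03e-12) and 18 of 25 mrps genes with a median of -0.445 (adjusted p = 1.09e-09). With an estimated correlation both had adjusted p = 0.613. At L1 the medians were -0.252 for mrpl (adjusted p = 0.000111) and -0.276 for mrps (4.64e-05), and adjusted p = 0.858 with an estimated correlation for both. Replicates 2 and 3 carried the L1 decrease: the mrpl mean read 9.11, 8.83 and 8.82 on the lin-35(n745) arrays against 9.10 to 9.18 in N2, and the mrps mean 8.89, 8.54 and 8.57 against at least 8.94. The GAPDH 5' minus 3' difference was -0.132, -0.375 and -0.524 on these lin-35(n745) arrays and -0.323, -0.0983 and -0.19 on those of N2. Whether RNA quality contributes was not tested. Of 40 glutathione transferase genes at L4, 15 were higher and 0 lower (median 0.218, adjusted p = 1.95e-07, and adjusted p = 0.362 with an estimated correlation).

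In embryos, of 58 nlp genes 28 were higher and 0 lower (median 0.442, adjusted p = 2.19e-19, and adjusted p = 0.0518 with an estimated correlation), and of 25 flp genes 15 and 0 (median 0.684, adjusted p = 2.78e-12, and adjusted p = 0.532 with an estimated correlation). The neuron list and other fixed lists hold 20 of these nlp genes and 21 of these flp genes, so the result is not separate from the neuron list. Over all families of at least 10 measured genes, 36 calls were made over the 3 stages, and 0 with an estimated correlation. In the camera tests of differences between stages, the hsp family passed with an estimated correlation for L1 against embryo and L4 against embryo. Its median differences were -0.341 (adjusted p = 3.13e-05, and adjusted p = 0.0253 with an estimated correlation) and -0.385 (1.15e-05 and 0.0146). For L4 against L1 it did not pass (-0.0722, adjusted p = 0.946).

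The X chromosome held 13.8% of the measured genes but fewer of the genes that were higher in lin-35(n745) larvae: 8.72% at L1 (Fisher's exact test, adjusted p = 2.72e-08) and 8.8% at L4 (8.04e-08), and 5.21% of those higher at all 3 stages (2.35e-05). In embryos the X held 14.5% of the genes that were higher (adjusted p = 0.654). Of the genes lower at L1 18.6% were on the X (adjusted p = 2.67e-05), and of those lower in embryos, at L4 and at all 3 stages 10.8% (0.0698), 15.9% (0.0698) and 5.66% (0.223). Chromosome II held 23.1% of the genes lower in embryos against 17.6% of those measured (adjusted p = 0.00125) and 35.8% of those lower at all 3 stages (0.00855). Chromosome III held 16.3% of the genes higher at L1 against 13.2% (0.00183). Chromosome V held fewer of the lower genes than of those measured, 20.7% at L1 (0.00125) and 20.2% at L4 (4.35e-05). Genes are not independent replicates in these tests.

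Genes higher at all 3 stages lay beside each other more often than expected from their number. In the WBcel235 annotation 14 pairs of neighbouring genes were both higher, against a median of 3 and at most 10 in 1000 permutations of the genes. Among genes whose probe sets are not marked as shared 8 pairs were found, against a median of 1 and at most 7. Among the pairs are inx-22 and inx-21, fbxa-162 and fbxa-163, tsp-1 and tsp-2, and lec-7 and lec-8, each of a single name family, and also zhp-2 and lotr-1, mus-101 and F37D6.3, and lig-1 and C29A12.1. The permutations drew genes at random, so they cannot show whether other sets of called genes hold as many neighbouring pairs. Why neighbouring genes were higher together was not tested. These 14 pairs leave open whether shared sequence between related genes adds to the count.

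Many genes differed widely among the lin-35(n745) L1 arrays, and the ones named here are examples, with no grouping of genes tested. The acyl-CoA dehydrogenase gene acdh-1 read 11.96, 4.32 and 9.80 on them, and the propionate breakdown gene hphd-1 11.13, 8.19 and 9.68. The nuclear receptor gene nhr-68 read 8.42, 5.17 and 7.27. In contrast, abu-6 read 8.06, 11.48 and 7.39 and abu-10 read 6.75, 9.84 and 6.16, low on replicates 1 and 3. grl-21 read 6.36, 10.03 and 6.70. At L1 7 of 11 abu genes were lower and 0 higher (median -0.889, -1.36 to -0.704 without single arrays, adjusted p = 0.00091, and adjusted p = 0.858 with an estimated correlation).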
